A study of Drosophila melanogaster with 3 samples.

How the data were processed

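RNA from Drosophila melanogaster larvae of the third instar was sequenced in 3 groups, females, males and metafemales. Metafemales carry an additional X chromosome beside the diploid autosomes. Per the labels, each group had 3 biological replicates, stocks were kept at 20 degrees, total RNA was extracted with TRIzol and libraries were made with the Illumina TruSeq RNA kit. Reads were aligned with TopHat and counted with HTSeq on the genome build dm3, per the submitters' processing notes. Their versions, the annotation release and the use of strand in counting are not given in the sources used here.

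The deposited values are fractions of each group's transcript counts, in 1 table of 3698 X-linked transcripts and 1 table of 19040 autosomal transcripts, with 3 columns each. Over both tables every column sums to 1, and the values were multiplied here to counts per 1000000 transcript counts (CPM). The authors gave 1 column per group and no column per replicate. Values below 0.05 CPM were whole-number combinations of 3 step sizes per column in 100% of 1749 female, 981 male and 2170 metafemale transcripts, within a relative tolerance of 1e-05. After a random change of 5% in each value, 0.515%, 0.102% and 0.968% still were. A column was therefore read as the mean over 3 libraries of count divided by library total. The steps give totals of 89.2, 74.4 and 65.6 M transcript counts for the female libraries, 92.4, 91.5 and 31.6 M for the male ones and 112, 99.6 and 69.0 M for the metafemale ones. These totals are inferred from the values and are not stated in a label.

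A mean of libraries with unequal totals has the counting error of 226 M (female), 169 M (male) and 269 M (metafemale) counts. The level that 3 counts give at this depth is 0.0133, 0.0178 and 0.0112 CPM. Intervals at 95% were computed from this depth (exact binomial, on the ratio of counts). They cover counting error only, not the spread between larvae, and reads without molecular identifiers are not independent molecules.

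The values read as if each read had been counted for every transcript it overlaps. Of 3962 genes with 2 or more transcripts, 523 had at least 2 transcripts with the same values. The transcript with the highest mean of the 3 columns therefore stood for its gene, and sums over transcripts were an alternative. This gave 14161 genes, 2238 of them in the X-linked table. Near-identical copies and overlapping genes share or split reads in unknown ways, among them AttA and AttB, Sgs7 and Sgs8, ng1 and ng2, the Hsp70 copies and the Lsp1 genes, and their single values are uncertain. The supplied annotation (Release 6) is of another build than dm3, so it was used only for current symbols, chromosome arms and gene order, and no coordinates are given. By accession 21508 transcripts matched, by name 1120, and 110 did not. Gene names that the tables hold as dates, such as Septin1, were matched by transcript. Of the transcripts in the autosomal table, 29 are placed on the X or the Y and were left out of the autosomal class. In 158 cases 2 or more gene names of the files are now 1 gene, such as Sxl and CG14425 or Hr4 and CG42527, and these were counted once within a gene list.

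Genes with a mean of at least 1 CPM were kept, which left 10942, of them 1734 X-linked and 9207 autosomal. Log2 fold changes were taken on value + 1 CPM, which understates the change of low genes. A gene was called higher or lower when this fold change reached 2-fold. The tests planned before the data were examined (a count model or a moderated linear model over 9 libraries, gene set tests on them, replicate blocks and fits without 1 library) need values per library, and none could be run on the pooled columns. No p-value is given and no difference has a replicate check. The difference between the median X-linked and the median autosomal fold change replaced the planned per-library difference, with a percentile bootstrap over genes that describes the precision across genes only.

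Before the data were examined, 24 gene lists were fixed: dosage compensation complex, sex determination, Y-linked genes, spermatocyte and testis genes, germline genes of both sexes, larval serum and fat body proteins, salivary gland glue and 71E genes, ecdysone response, antimicrobial peptides and immune induction, heat shock and protein folding, cell stress, detoxification, digestive enzymes, muscle structure, larval cuticle, haemocytes, neurons and synapse, imaginal disc patterning, growth and insulin/TOR signalling, glycolysis and sugar metabolism, ribosomal proteins, oxidative phosphorylation, proteasome, and chromatin regulators. The median of each list with at least 5 kept members was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A scaling factor moves a list and its random lists alike, apart from the added 1 CPM. The Y-linked list had no kept member, so 23 lists were placed. If list members varied independently, 1.15 of these lists would lie outside the central 95% by chance. Members that vary together would put more lists outside, so 1.15 is no yardstick for the number found there. Of the 762 listed genes, 8 stood in 2 or more lists.

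Genes named in the text were chosen by a rule fixed before the data were examined, with fold change in place of the planned test: the 10 highest and 10 lowest fold changes with at least 5 CPM in the higher group (5 and 5 for metafemales against males), the 3 highest and 3 lowest X-linked ones, the dosage compensation genes with Sxl, tra and dsx, and up to 4 members per list with the largest fold change. Other members of a list that are named were chosen after their values were seen. Alternatives tried were a pseudocount of 0.1, no filter, a minimum of 10 CPM, median-of-ratios scaling on all or on autosomal genes, other treatments of the transcripts, and rules of 1.5-fold and 4-fold. The steps were tested on data simulated from the female column for metafemales against females, with 9545 genes. These data held counting error but no spread between libraries, and folds were planted only in genes with a mean of at least 10 CPM. The shares that follow are therefore not error rates for real libraries. All genes planted at 2.5-fold (45) and 4-fold higher (43) or 4-fold lower (38) were called (100%) and 0% of 9345 others, and an X-linked log2 shift planted at 0.38 came back as 0.36 on the value + 1 scale. In a simulation of males against females, 3.33% of 60 lists of randomly drawn genes lay outside the central 95%. Such lists do not test genes that vary together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.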

Results

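The data are 1 expression value per transcript for each of 3 groups of whole larvae: females with the usual pair of X chromosomes, males with 1, and metafemales with 3. Each value pools 3 libraries, whose inferred totals ran from 65.6 to 89.2 M transcript counts in females, from 31.6 to 92.4 M in males and from 69.0 to 112 M in metafemales. Values are counts per 1000000 transcript counts (CPM), log2 fold changes and ranks by size are on value + 1 CPM. Intervals cover counting error only, and no difference between groups has a replicate check. Libraries of a group differed by more than counting error among low values (below 0.05 CPM). There the mean chi-square per degree of freedom was 1.78 in females, 1.43 in males and 2.16 in metafemales. The deepest metafemale library held 61.9% of those low counts against 39.9% by its depth. The spread between libraries at the higher levels of the genes kept was not measured. X-linked transcripts took 16.2% of counts in females, 14.8% in males and 19.6% in metafemales, with every transcript of a gene counted.

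The series asks how expression in metafemales compares with that in normal females. Lists of salivary glue, ecdysone response, proteasome and ribosomal protein genes had medians below those of matched genes in metafemales against females. Lists of glycolysis, muscle, detoxification and digestion genes had medians above them. Medians of imaginal disc and heat shock lists were below as well. For genes with a mean of at least 10 CPM both lay inside the central 95% of random lists (percentiles 3.24 and 3.28). The antimicrobial median was also below, but was so in males against females too (-1.13). In metafemales against males it stood at percentile 65.15. In none of the lists named here did all members pass the 2-fold rule. CG11350 had the largest increase over females, from 1.53 to 563 CPM (369-fold, 332 to 411). ImpE2, an ecdysone-inducible gene of imaginal discs, had 130 CPM in females and 0.497 in metafemales, 261-fold lower. Of 10942 genes, 526 were at least 2-fold higher in metafemales, 1188 were at least 2-fold lower and the median of all genes was -0.22 (log2).

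This split turned with the scaling. Median-of-ratios scaling changed the ratio of the groups by 0.36 (log2, before 1 CPM is added) and gave 895 higher and 536 lower genes. Scaling on autosomal genes changed it by 0.44 and gave 1001 and 459, and relative to the median of all genes 759 were higher and 679 lower. Each list median named below as outside the random lists stands against matched genes of the same comparison, which a scaling factor moves alike apart from the added 1 CPM. Counts of members past 2-fold do depend on scaling, and a pair of counts called rescaled gives them with median-of-ratios and with autosomal scaling.

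Glue and 71E genes, which are expressed in the larval salivary gland, split in metafemales: 6 of 12 were lower (rescaled 6 and 6), 3 higher (4 and 4) and 3 within 2-fold, with a median of -1.25 that lay below all 10000 random lists. Sgs8 had 923 CPM in females and 26.7 in metafemales (-5.06), Sgs1 had 178 and 7.15 (-4.46), Sgs7 had 2783 and 185 (-3.91) and Sgs5 had 3513 and 323 (-3.44). The 3 higher members were ng1 (9.82 and 53.3), ng2 (11.8 and 66.1) and ng3 (278 and 878), which are X-linked salivary gland genes transcribed before the glue genes. CG7587 (Sgs5bis) was also lower, at 115 CPM in females and 2.07 in metafemales.

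In the ecdysone list, 17 of 32 genes were lower (rescaled 9 and 9), 2 higher (3 and 4) and 13 within 2-fold, and the median of -1.04 lay below all random lists. ImpE1 had 36.7 CPM in females and 2.55 in metafemales (-3.41), Eip78C had 18.2 and 1.18 (-3.14), and the X-linked nuclear receptor gene Hr4 (CG42527 in the deposited table) had 23.6 and 1.15 (-3.51). The higher members were ImpL3, which encodes lactate dehydrogenase (65.5 and 182), and Hr38 (1.75 and 4.77). Imaginal disc regulators followed, with 16 of 31 lower (rescaled 6 and 4), 0 higher and 15 within 2-fold and a median of -1.01 below all random lists, but inside their central 95% (percentile 3.24) for the 9 genes with a mean of at least 10 CPM. Dachshund (dac, -1.90), Distal-less (Dll, -1.66), engrailed (en, -1.53) and vestigial (vg, -1.50) were the lowest among them.

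Immune genes were lower too, with 19 of 30 members lower (rescaled 16 and 16), 2 higher and 9 within 2-fold (median -1.34, below all random lists, as was the median of -1.13 in males against females). The attacins AttA (42.2 and 0.913 CPM), AttB (17.7 and 0.839) and AttC (23.7 and 0.900) and the drosomycin-like dro5 (13.3 and 0.197) led this group, and TotC (10.7 and 30.6) and PGRP-SC1a (2.12 and 6.10) were the higher members. The small heat shock genes Hsp26 (-4.32), Hsp23 (-4.06), Hsp27 (-3.25) and Hsp67Bc (-2.57) were lowest in a list with 10 of 22 lower (rescaled 9 and 9), 0 higher (1 and 1) and 12 within 2-fold (median -0.71, percentile 0.59, but 3.28 and inside the central 95% for genes with a mean of at least 10 CPM). Proteasome subunits had 14 of 31 lower (rescaled 7 and 5), 0 higher and 17 within 2-fold around a median of -0.97, for example Prosalpha5 (-1.70) and Rpn12 (-1.66). Ribosomal proteins had 26 of 92 lower (rescaled 0 and 0), 0 higher and 66 within 2-fold around a median of -0.68 (-0.33 and -0.25 with the other scalings), with RpL21 (-1.27), RpL41 (-1.27) and RpL38 (-1.26) lowest, and both medians lay below all random lists. In the cell stress list (median -0.53, percentile 0.85, but inside the central 95% with autosomal members only, 2.52, or a mean of at least 10 CPM, 3.94) 8 of 32 were lower (rescaled 5 and 5), among them Gadd45 (41.0 and 8.63) and Ets21C (14.1 and 2.01), 23 were within 2-fold, and CG14059, which encodes the insulin-like peptide Ilp8, was the 1 higher gene (rescaled 2 and 3) at 0.589 and 4.27 CPM.

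Muscle genes had 12 of 26 higher (rescaled 19 and 20), 0 lower and 14 within 2-fold, and their median of 0.92 lay above all random lists. Mhc, the muscle myosin heavy chain, had 676 CPM in females and 3709 in metafemales (2.45), the muscle actin Act57B had 1408 and 7532 (2.42) and Unc-89 had 39.3 and 162 (2.02). Glycolysis and sugar metabolism had the same shape, with 12 of 25 higher (rescaled 16 and 16), 0 lower and 13 within 2-fold and a median of 0.94 above all random lists. Gpo-1 (17.4 and 79.7), the glycogen phosphorylase gene GlyP (212 and 777) and the pyruvate kinase gene PyK (145 and 422) were among the highest.

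Storage and fat body genes had 7 of 22 higher (rescaled 8 and 8), 1 lower and 14 within 2-fold (median 0.23, percentile 99.4, but 0.07 and 96.6, inside the central 95%, with autosomal members only). Lsp1beta, a larval serum protein, had 4342 CPM in females and 17148 in metafemales (1.98), Lsp1alpha on the X had 474 and 2700 (2.51) and the fatty acid synthase gene CG3523 had 213 and 944 (2.14). Fbp1, the receptor for these serum proteins, was the 1 lower member, at 6045 and 1108 (-2.45). Haemocyte genes had 7 of 18 higher (rescaled 8 and 8), 1 lower and 10 within 2-fold (median 0.23, percentile 99.9), with the prophenoloxidases CG8193 (PPO2, 29.8 and 177) and proPO-A1 (26.8 and 128) higher and nimC2 lower (78.0 and 18.2).

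Detoxification genes had 14 of 55 higher (rescaled 22 and 22), 1 lower (0 and 0) and 40 within 2-fold around a median of 0.37, for example Cyp6a2 (1.19 and 8.66) and Cyp28a5 (9.62 and 34.0), and GstD3 was the 1 lower gene (16.4 and 7.15). Digestive enzymes had 12 of 50 higher (rescaled 18 and 18), 4 lower (2 and 2) and 34 within 2-fold around 0.36, with betaTry at 207 and 877 CPM and the lysozyme LysX at 40.5 and 2.73. Larval cuticle genes went both ways, with 9 of 31 higher (rescaled 14 and 16), 5 lower (4 and 4) and 17 within 2-fold around 0.58. Among its members Cpr62Bc (3.67) and Cpr67Fa1 (3.44) were higher, as was Cpr47Eg outside the list (4.33), and Pcp (-3.67), Cpr49Ac (-2.82), Cht5 (-2.70) and Lcp1 (-2.24) lower. Oxidative phosphorylation had 5 of 89 higher (rescaled 18 and 21), 0 lower and 84 within 2-fold around 0.12, with ND75 (1.51) and blw (232 and 658 CPM) highest. These 4 medians lay above all random lists, although cuticle genes with a mean of at least 10 CPM lay inside the central 95% (0.05, percentile 96.8). The median of 25 neuronal genes, all within 2-fold (rescaled 1 and 2 higher), was 0.01 (percentile 99.3), but inside the central 95% for the 16 autosomal members (96.8) and with at least 10 CPM (87.3).

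Other lists lay within the central 95% of random lists in metafemales against females. They were the dosage compensation complex (9 of 9 within 2-fold, median -0.33, but 0.04 with autosomal scaling) and sex determination (4 of 18 lower, rescaled 2 and 2, 1 higher, 13 within, -0.55, but -0.21 and -0.13 with the other scalings). Spermatocyte and testis genes also lay within (3 of 40 lower, 0 higher, 37 within 2-fold, -0.20, but -0.10 and -0.09 with the other scalings). With 0.1 CPM added in place of 1, the testis list had 15 lower and a median of -0.61, outside at percentile 0.64. Others were germline genes (16 of 16 within, -0.19, but 0.06 with autosomal scaling), growth signalling (2 of 25 lower, rescaled 0 and 0, 1 higher, 22 within, -0.34, but 0.01 and 0.09 with both other scalings) and chromatin regulators (3 of 39 lower, rescaled 1 and 1, 0 higher, 36 within, -0.49, but -0.14 and -0.06 with the other scalings). The lower sex determination genes were Yp2 (12.6 and 0.594 CPM), sc (6.39 and 0.795), dsx (9.82 and 3.98) and snf (41.0 and 19.5), and fru was higher (12.5 and 26.7). The lower testis list members were heph (69.8 and 21.9), mip40 (-1.49, log2) and Mst87F (2.30 and 0.329), and the lower growth genes were ImpL2 (57.9 and 23.9) and CG18619 (38.8 and 16.0). The lower chromatin genes were the gene of heterochromatin protein HP1a (93.7 and 31.8), HP1c and BEAF-32, of which only the first stayed lower with the other scalings (-1.18 and -1.10). The dosage compensation genes msl-1 (-0.33), msl-2 (-0.30), msl-3 (-0.42), mle (-0.38), mof (0.28), roX1 (-0.21) and roX2 (-0.19) and the sex switch gene Sxl (-0.25) were within 2-fold, roX2 only because of the added 1 CPM (0.181 and 0.0339, 5.34-fold lower without it), and msl-1, msl-2, roX1 and Sxl turned positive under both other scalings.

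Of genes outside the lists, CG10953 (0.946 and 83.3 CPM), CG32241 (1.09 and 88.5), CG32198 (9.44 and 197), CG13705 (0.226 and 24.9), CG7214 (1.76 and 43.8) and CG30457 (0.617 and 24.5) had the largest increases over females. On the X these were CG32603 (5.69 and 226), CG32564 (3.95, log2) and CG6788 (0.595 and 22.9). CG42500 (706 and 6.66), CG5391 (282 and 4.17), CG17386 (50.3 and 0.867), CG34193 (21.5 and 0.0424) and the X-linked CG2444 (844 and 20.1) were lowest against females.

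**Figure D1:**
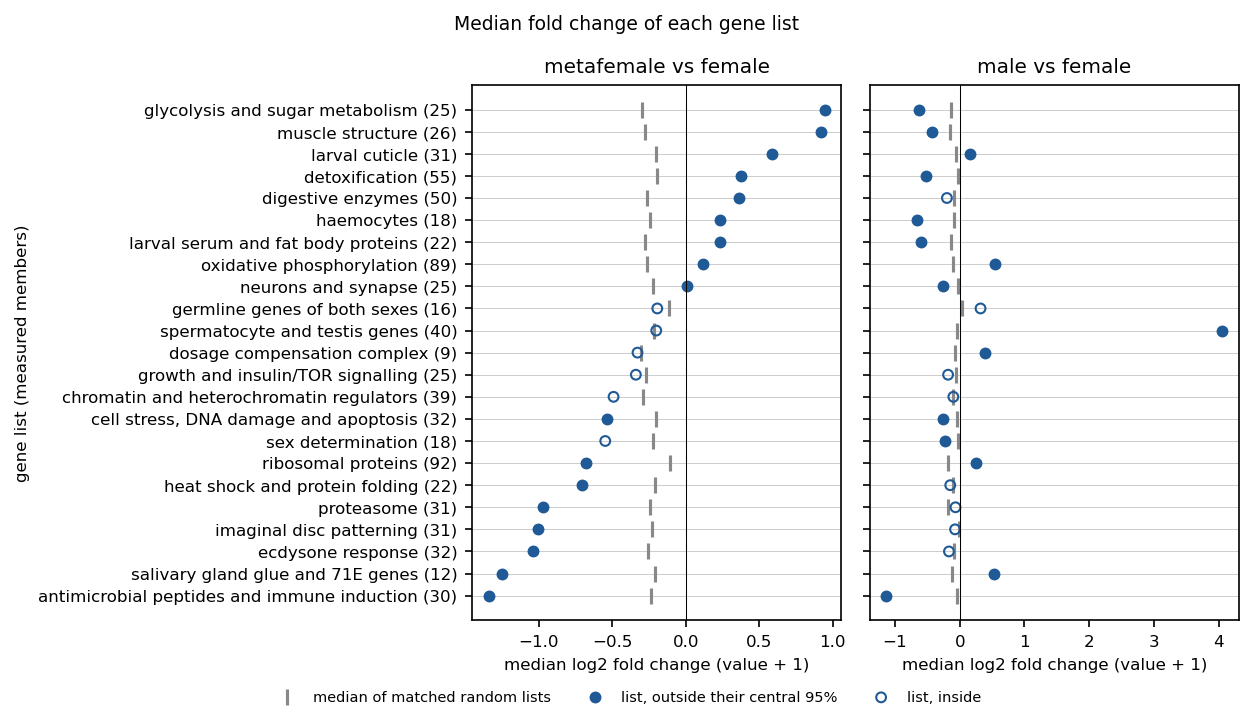
Median log2 fold change (x axis, value + 1 CPM) of each gene list (y axis, number of measured members in brackets) in metafemales and in males against females. Dots are list medians, filled when outside the central 95% of 10000 matched random lists, and grey bars are the medians of those random lists; in metafemales antimicrobial genes (-1.34) and glycolysis (0.94) mark the ends, in males testis genes stand at 4.05.

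In metafemales against females the median X-linked gene stood above the median autosomal gene. A scaling factor moves both classes alike apart from the added 1 CPM, so scaling is no check on the sign of this difference. The level of either class depends on scaling. As deposited, the X-linked median was 0.03 (log2; middle 50% of genes -0.23 to 0.38), with 54.2% of 1734 genes above 0, and the autosomal median was -0.29 (-0.69 to -0.01) over 9207 genes. Among X-linked genes 134 (7.73%) were at least 2-fold higher and 58 (3.34%) lower, and among autosomal genes 392 (4.26%) and 1130 (12.3%). These counts are as deposited and depend on scaling, like the split of all genes. The X-linked median exceeded the autosomal one by 0.32 (0.29 to 0.34 by bootstrap over genes) and lay above all 10000 matched autosomal lists.

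Among genes with at least 10 CPM, the median ratio of metafemales to females was 1.05 for X-linked and 0.742 for autosomal genes, and the peaks of the 2 distributions lay at 1.04 and 0.758. Median-of-ratios scaling placed the X-linked median at 0.33 and the autosomal one at -0.04, and scaling on autosomal genes placed them at 0.40 and -0.01. The offset between the classes stayed between 0.17 and 0.46 over 12 alternatives. Autosomal arms had medians of -0.29 (2L), -0.28 (2R), -0.30 (3L), -0.29 (3R) and -0.38 (chromosome 4), and 10 consecutive blocks of X-linked genes lay 0.28 to 0.44 above the autosomal median.

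Within functional groups the X-linked members were also the higher ones in most cases. Over 18 lists with at least 2 members of each class, 15 had the X-linked median above the autosomal one. X-linked ribosomal protein genes had a median of -0.28 (15 genes) and autosomal ones -0.87 (77 genes). In oxidative phosphorylation the medians were 0.68 (13 genes) and 0.02 (76 genes), with the X-linked ND75, a subunit of complex I, at 53.7 CPM in females and 155 in metafemales. X-linked proteasome genes stood at -0.52 (4 genes) and autosomal ones at -0.98 (27 genes). Haemocytes, glycolysis and sex determination had the lower X-linked median.

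**Figure D2:**
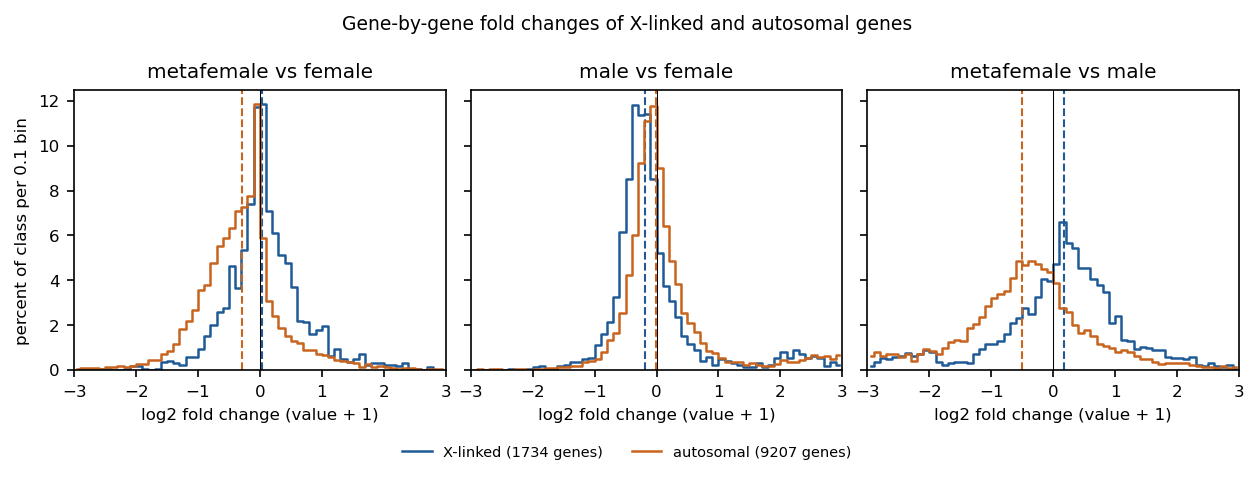
Distribution of log2 fold changes (x axis, value + 1 CPM; y axis, percent of the class per bin) of 1734 X-linked and 9207 autosomal genes in each comparison. Dashed lines are class medians: 0.03 and -0.29 for metafemales against females, -0.19 and -0.01 for males against females, 0.18 and -0.50 for metafemales against males.

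**Figure D3:**
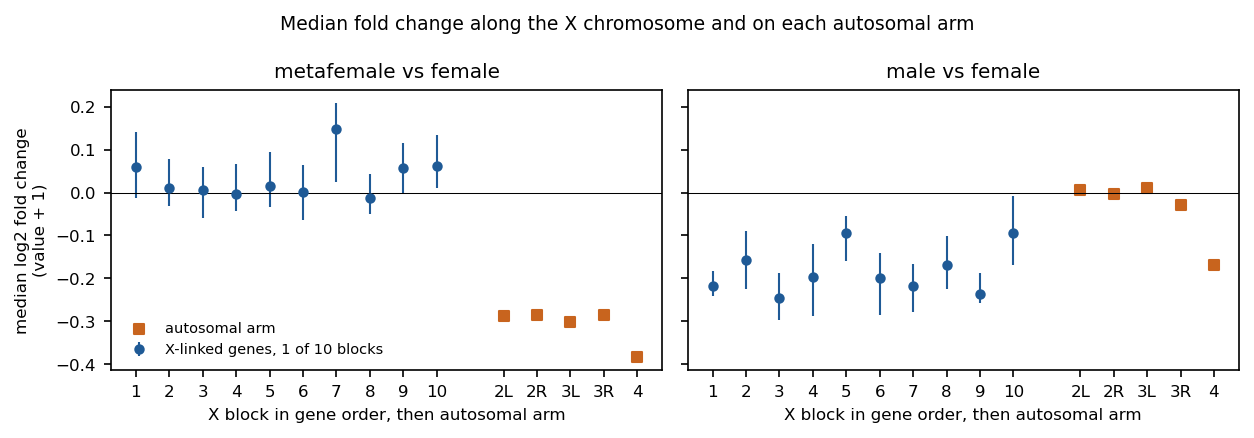
Median log2 fold change (y axis, value + 1 CPM) of 10 equal blocks of X-linked genes in gene order and of each autosomal arm (x axis), in metafemales and in males against females. Bars on the blocks are 95% bootstrap intervals over genes. Each X block stands above all autosomal arms in metafemales. In males the X blocks and chromosome 4 (-0.17) stand below 0, as do 3R (-0.028) and 2R (-0.0024) by less.

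Males against females give the other end of the X dosage series. Most genes of the developing testis list were far higher in males, together with the dosage compensation RNAs roX1 and roX2. Lists of antimicrobial, fat body, glycolysis, detoxification and haemocyte genes had medians below those of matched genes, with most members within 2-fold in all of them but the antimicrobial list. Of 10942 genes 1670 were at least 2-fold higher and 214 lower, with a median of all genes of -0.04. Both other scalings changed the ratio of the groups by less than 0.1 (0.07 and 0.04) and gave 1691 and 1657 higher genes against 179 and 190 lower ones.

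Of 40 spermatocyte and testis genes 36 were higher in males, 0 lower and 4 within 2-fold, and their median of 4.05 lay above all random lists. Among the highest were leucyl aminopeptidases of sperm, CG6372 (S-Lap1, 0.891 CPM in females and 249 in males), CG13340 (S-Lap7, 0.517 and 197) and CG32064 (S-Lap4, 0.519 and 185). Also among them were loopin-1 (0.604 and 204) and betaTub85D, the testis beta-tubulin (0.621 and 155). CG4836 had the largest log2 fold change of all genes (7.36), at 376 CPM in males and 290-fold without the added 1 CPM (258 to 326), and genes with lower female values such as CG4439 (383-fold) had larger plain folds. Next to it, CG32063 (S-Lap3), CG4439 (S-Lap8), CG12699 and SIP2 (salto) were also among the 10 largest. In the germline list 3 of 16 genes were higher, 0 lower and 13 within 2-fold (median 0.32, percentile 89.6): orb (0.906 and 36.4), bgcn (0.372 and 7.14) and stil (0.216 and 3.75).

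Oxidative phosphorylation had 22 of 89 genes higher, 0 lower and 67 within 2-fold (median 0.55), and ribosomal proteins had 9 of 92 higher, 0 lower and 83 within 2-fold (0.25), both above all random lists. The highest were paralogs of the common subunits. CG10396 (COX4L) had 0.187 CPM in females and 27.5 in males, CG18193 (COX7AL) had 0.127 and 17.5, RpL37b had 0.0382 and 12.8, RpS19b had 0.492 and 13.5 and RpL22-like had 0.171 and 9.79.

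In the dosage compensation list 3 of 9 genes were higher, 0 lower and 6 within 2-fold (median 0.40, percentile 99.1, but 94.5 and inside the central 95% for the 6 autosomal members). The noncoding RNA roX1 had 20.7 CPM in females and 388 in males (18.8-fold), roX2 had 0.181 and 50.5 (279-fold) and msl-2, the male-limiting subunit of the complex, had 7.62 and 20.8 (2.73-fold). The other subunits were within 2-fold, mof at 0.50, msl-3 at 0.34, mle at 0.26 and msl-1 at 0.00 (log2). Pof, whose protein binds chromosome 4, had 7.77 CPM in females and 74.5 in males and was the 1 higher gene of 39 chromatin regulators, with 0 lower and 38 within 2-fold (median -0.10). CG8565 (0.227 and 56.1) and CR32690 (0.179 and 52.7) were, with roX2, the highest X-linked genes.

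Sex determination genes had 3 of 18 lower, 0 higher and 15 within 2-fold (median -0.23, percentile 1.34, but -0.12 and 16.4, inside the central 95%, with autosomal members only). Sxl had 103 CPM in females and 27.3 in males (-1.88), dsx had 9.82 and 3.88 (-1.15), the yolk protein gene Yp2 had 12.6 and 0.523 (-3.16) and tra had 5.82 and 2.88 (-0.81, within 2-fold on the value + 1 scale). The lowest X-linked genes were eag, a potassium channel gene (28.7 and 0.642), CG9981 (37.5 and 1.37) and CG9360 (21.0 and 0.803), and the X-linked Ser6 (11.3 and 0.0939) and CG1304 (10.7 and 0.0688) were also among the 10 lowest, with the autosomal CG12374 and CG6188 (Gnmt).

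Antimicrobial genes had 16 of 30 lower in males, 0 higher and 14 within 2-fold (median -1.13), for example IM1 (49.1 and 2.75), AttC (23.7 and 1.37), IM4 (19.8 and 1.63) and TotC (10.7 and 0.583). Storage and fat body genes had 5 of 22 lower, 0 higher and 17 within 2-fold (-0.60), among them Fbp2 (1227 and 284), the X-linked transferrin gene Tsf1 (246 and 64.5) and Lsp1beta (4342 and 1505). Glycolysis had 5 of 25 lower, 0 higher and 20 within 2-fold (-0.63), led by tobi (7.39 and 0.800), and detoxification had 7 of 55 lower, 0 higher and 48 within 2-fold (-0.52), led by Cyp6a8 (12.4 and 3.23). Haemocyte genes had 4 of 18 lower, 1 higher and 13 within 2-fold (-0.65), with Hml at 90.9 and 32.7 CPM and gcm the higher one (0.325 and 7.60). These 5 medians lay below all random lists.

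Muscle genes (1 of 26 higher, Mlp60A, 1 lower, Unc-89, 24 within 2-fold; median -0.43, percentile 0.03), neuronal genes (25 of 25 within 2-fold, -0.27, percentile 0.30) and cell stress genes (5 of 32 lower, 0 higher, 27 within, -0.25, percentile 0.28, but 5.10 and inside with at least 10 CPM) also lay below the central 95%. Glue and 71E genes lay above it (1 of 12 higher, Eig71Ea, 2 lower, ng1 and ng2, 9 within, 0.53, above all but 1 of the random lists), with Sgs8 at 923 and 1846 CPM. Cuticle genes (6 of 31 higher, 0 lower, 25 within, 0.15) lay exactly at its upper limit and are counted as outside, but lay inside with autosomal members only (percentile 91.5) and with at least 10 CPM (85.6). Inside it lay ecdysone genes (3 of 32 higher, Eip78C, Hr46 and Hr4, 1 lower, ImpL3, 28 within, -0.17). Also inside were digestion (8 of 50 lower, 0 higher, 42 within, -0.20), heat shock (3 of 22 lower, 0 higher, 19 within, -0.15), growth signalling (1 of 25 lower, Myc under the name dm, 0 higher, 24 within, -0.18), imaginal discs (31 of 31 within, -0.07) and the proteasome (31 of 31 within, -0.07, but 0.00 with median-of-ratios scaling). The lower heat shock genes were stv and the near-identical Hsp70Bb and Hsp70Bbb, and the lower stress genes were Gadd45, Ets21C, upd3, A3-3 and GstD2.

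The median X-linked gene was -0.19 in males against females (31.2% of genes above 0) and the median autosomal gene -0.01 (49.1% above 0). The difference of -0.19 (-0.20 to -0.16) lay below all matched autosomal lists and stayed between -0.32 and -0.11 over 12 alternatives. Among genes with at least 10 CPM the median male to female ratio was 0.834 for X-linked and 0.954 for autosomal genes. The sign of the autosomal median turned with scaling (0.05 and 0.02), and the X-linked median was -0.13 and -0.16.

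Metafemales against males set 3 X chromosomes against 1. Nearly all testis genes and the roX RNAs were lower in metafemales, and more than 50% of the muscle, glycolysis and detoxification genes were at least 2-fold higher. Of 10942 genes 942 were at least 2-fold higher and 3126 lower around a median of -0.40. Median-of-ratios scaling changed the ratio of the groups by 0.29 (log2) and gave 1342 and 2496, and scaling on autosomal genes changed it by 0.40 and gave 1532 and 2313. CG11350 (0.740 CPM in males and 563 in metafemales), CG32603 (3.62 and 226), CG10953 (0.890 and 83.3), TepI (0.731 and 75.9) and CG32198 (3.48 and 197) had the largest increases over males, and CG4836, CG6372, CG13340, loopin-1 and CG32064 were lowest.

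Of 40 testis genes 39 were lower in metafemales than in males, 0 higher and 1 within 2-fold (median -4.15). The roX1 RNA was 21.9-fold lower, roX2 was 1492-fold lower (0.0339 CPM in metafemales) and msl-2 was 3.46-fold lower, while Sxl was 3.17-fold higher, tra stood at 0.19 and dsx at 0.03 (log2). Glycolysis had 18 of 25 higher, 0 lower and 7 within 2-fold (1.57), muscle 17 of 26 higher, 0 lower and 9 within (1.32), detoxification 30 of 55 higher, 1 lower and 24 within (1.10) and storage and fat body genes 10 of 22 higher, 1 lower and 11 within (0.79), with Lsp1beta 11.4-fold and Gpo-1 10.7-fold higher and Mhc at 3.32 (log2). The other lists above the central 95% were haemocytes (8 of 18 higher, 2 lower, 8 within, 0.80), digestion (16 of 50 higher, 3 lower, 31 within, 0.54), cuticle (7 of 31 higher, 6 lower, 18 within, 0.28) and neurons (3 of 25 higher, 0 lower, 22 within, 0.21), of which cuticle and neurons lay inside it for genes with at least 10 CPM (percentiles 83.7 and 97.3). Testis genes, ribosomal proteins (49 of 92 lower, 0 higher, 43 within, -1.06), the proteasome (13 of 31 lower, 0 higher, 18 within, -0.90) and glue genes (7 of 12 lower, 3 higher, 2 within, -1.77) lay below it. Rescaled counts of lower members were 37 and 36 for testis genes, 37 and 33 for ribosomal proteins, 6 and 4 for the proteasome and 7 and 7 for glue genes. Those of higher members were 21 and 22 for glycolysis, 19 and 20 for muscle, 34 and 35 for detoxification, 12 and 13 for storage and fat body genes, 10 and 10 for haemocytes, 20 and 23 for digestion, 10 and 10 for cuticle and 5 and 5 for neurons. Lower members of digestion were 1 and 1 and of cuticle 6 and 5, and higher ribosomal proteins 1 and 2. ImpE2 was 444-fold and Hsp26 27.1-fold lower than in males.

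The remaining lists lay inside the central 95% in metafemales against males. Ecdysone genes (13 of 32 lower, rescaled 13 and 11, 4 higher, rescaled 5 and 5, 15 within, median -0.64) had a negative median under every scaling. So did imaginal disc regulators (11 of 31 lower, rescaled 8 and 6, 0 higher, 20 within, -0.85) and germline genes (6 of 16 lower, rescaled 4 and 4, 0 higher, 10 within, -0.62). Oxidative phosphorylation (31 of 89 lower, rescaled 24 and 22, 12 higher, rescaled 19 and 20, 46 within, -0.45), chromatin regulators (6 of 39 lower, rescaled 4 and 3, 0 higher, 33 within, -0.42) and heat shock genes (7 of 22 lower, rescaled 7 and 7, 0 higher, rescaled 1 and 1, 15 within, -0.39) also had negative medians under every scaling, like the dosage compensation list (4 of 9 lower, rescaled 3 and 3, 0 higher, 5 within, -0.89), whose lower members were roX1, roX2, msl-2 and JIL-1. The median of antimicrobial genes (6 of 30 lower, rescaled 6 and 5, 3 higher, rescaled 6 and 7, 21 within, -0.31) turned positive with autosomal scaling (0.02). So did the medians of cell stress genes (6 of 32 lower, rescaled 3 and 3, 4 higher, rescaled 7 and 7, 22 within, -0.32), sex determination genes (2 of 18 lower, rescaled 1 and 1, 3 higher, rescaled 3 and 3, 13 within, -0.24) and growth genes (1 of 25 lower, rescaled 1 and 1, 2 higher, rescaled 2 and 4, 22 within, -0.09), at 0.03, 0.12 and 0.29. TotC (0.583 CPM in males and 30.6 in metafemales), IM4 (1.63 and 16.6), fru (7.45 and 26.7) and Myc (dm, 17.8 and 44.9) were among the higher members.

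In this comparison X-linked genes had a median of 0.18 (0.44 and 0.54 with the other scalings) and autosomal genes one of -0.50 (-0.24 and -0.14). The offset of 0.68 (0.63 to 0.72) stayed between 0.41 and 0.75 over 12 alternatives. Among genes with at least 10 CPM, the peaks of the ratio distributions lay at 1.23 for X-linked and 0.763 for autosomal genes.

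**Figure D4:**
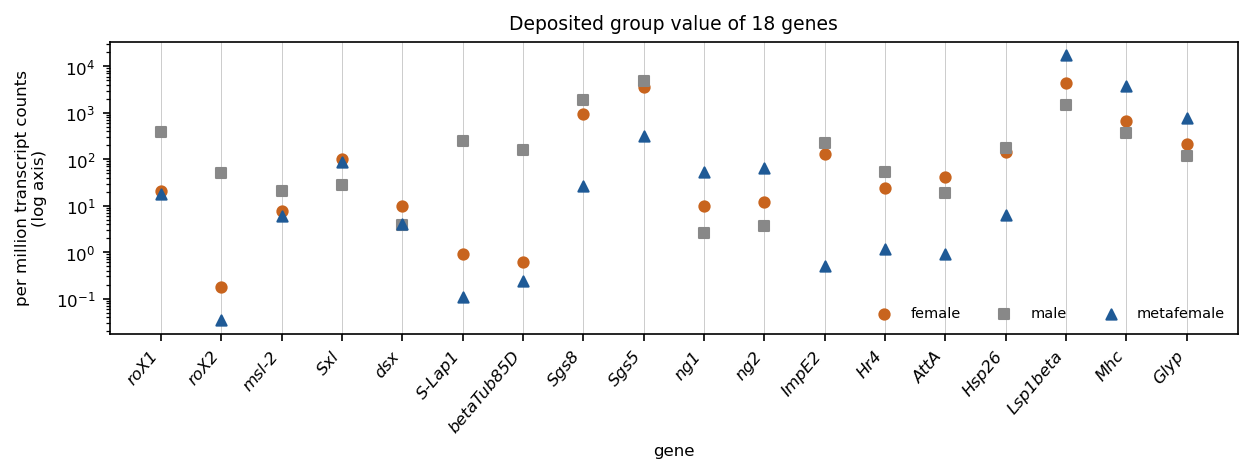
Deposited group value (y axis, CPM, log axis) of 18 genes (x axis) in females, males and metafemales. The roX RNAs and testis genes stand highest in males, and Sgs8, ImpE2 and AttA stand lowest in metafemales (26.7, 0.497 and 0.913 CPM).

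Genes that departed from the female level in metafemales were set against those that did so in males. In both, 13 genes were at least 2-fold higher and 49 were lower. Higher in metafemales and lower in males were 73 genes, and lower in metafemales and higher in males were 49. Independent lists would share 80.3, 23.2, 10.3 and 181 genes, in the same order. These counts are rough guides, since both comparisons use the same female value. An error in that value moves both fold changes the same way, so on its own it puts no gene in the opposite-direction counts. In addition, a gene with less than 1 CPM in females, as most testis genes have, cannot pass 2-fold lower on value + 1 CPM. Across genes, which are not independent replicates, the correlation of the 2 fold changes was -0.02 (0.02 for autosomal genes) and the covariance -0.0159. In 100 simulations with counting error alone they were 0.485 and 0.000777, and no gene reached 2-fold in both. The simulated correlation comes from the shared female value in columns without any difference, so it is no yardstick for the observed one. The covariance less the simulated one was -0.0167. The female libraries are pooled in 1 column and could not be split, so how much of the overlap in the same direction comes from the shared female value could not be measured.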

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

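The test weighed in this part was chosen only after the result had been seen. Transcripts of Y-linked genes, which females do not carry, summed to 0.368 counts per 1000000 transcript counts (CPM) in the female column, a signal in genes that no comparison covers. They summed to 16.3 CPM in males and to 0.0461 in metafemales. Of 21 Y-linked genes, 21 had a value above 0 in males, 11 in females and 1, CG41503, in metafemales. The largest part of the female sum came from CG41503 (0.116 in females and 0.841 in males), followed by the fertility genes kl-3, kl-2 and kl-5, whose reads the value steps place in more than 1 female library. ARY, the highest Y-linked gene in males (2.78), had 0 in females.

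The Y-linked sum in females was 2.26% of the male one (1.79 to 2.81), and 1.63% without CG41503 (1.24 to 2.13). If male larvae or male reads with the makeup of the male column were the only source, roX2 should stand at the same percentage of its male level, but it stood at 0.358% (0.258 to 0.489), and the median of 35 testis genes stood at 0.423%. The test therefore argues against such a source alone for the sum. Gene by gene the values are too low to decide, since the median Y-linked gene stood at 0.383% (Pp1-Y2), and 23 of the 35 testis genes, not all, had an upper bound below the lower bound of the Y-linked sum. Reads that fit both the Y and other repeated sequence, or male tissue of another makeup, may contribute and were not tested. The values for each library separately were not analysed here, so the library of origin is known only for the lowest values.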

How the results depend on the processing

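No paired analysis was possible because each group is given as 1 pooled column. For the same reason the planned count-model tools, replicate block, fits without 1 replicate, adjusted p limits and rotation or correlation-adjusted list tests were not run. Chosen after seeing the data were the 1.5-fold and 4-fold rules, the transcript treatments, the pseudocount, scaling or filter for results that had not planned them, and all list alternatives but autosomal members only. No named gene past the 2-fold rule changed sign, though 638 of 1318 values of all named genes moved beyond their counting interval. The unchanged sign is a weak check. Another pseudocount cannot turn a sign, and the scalings changed the ratio of 2 groups by 0.44 (log2) at most, less than the 2-fold rule. Signs did change among values within 2-fold, such as msl-1, msl-2, roX1 and Sxl in metafemales against females, 8 list medians and the autosomal median of males against females. Where a value below differs from the main one the cause was not tested, except that another scaling multiplies all values of a group alike (before 1 CPM is added) and another fold rule or minimum changes which genes are counted.

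Genes past the size rule in metafemales against females numbered 1714, and 4044 with 1.5-fold, 255 with 4-fold and 2674 with every transcript counted singly. In males against females they numbered 1884, and 2924 with 1.5-fold and 456 with a minimum of 10 CPM. In metafemales against males they numbered 4068, and 6252 with 1.5-fold, 1889 with 4-fold, 1834 with a minimum of 10 CPM and 6263 with every transcript. Genes past the rule in the same direction in metafemales and in males against females numbered 62, and 188 with 1.5-fold and 13 with 4-fold. Scaling left these counts within 1.5 times but turned the split of metafemales against females, from 30.7% higher to 62.5% (median of ratios) or 68.6% (autosomal genes). Against males it went from 23.2% higher to 35.0% and 39.8%.

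The X-linked minus autosomal offset (log2) kept its sign everywhere, which the scalings could not turn apart from the added 1 CPM. In metafemales against females it was 0.32, and 0.40 as a mean over genes, 0.46 from deviations from each gene's mean (the formula first planned), 0.44 with a pseudocount of 0.1, 0.17 without filter, 0.45 with a minimum of 10 CPM, 0.37 with median-of-ratios scaling, 0.41 with autosomal scaling, 0.29 for genes with 1 transcript and 0.35 with every transcript. In males against females it was -0.19, and -0.32 as a mean, -0.21 from deviations and -0.11 without filter. In metafemales against males it was 0.68, and 0.75 with a pseudocount of 0.1 and 0.41 without filter.

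The X-linked median of metafemales against females was 0.03, and 0.072 with a minimum of 10 CPM, 0.33 with median-of-ratios scaling, 0.40 with autosomal scaling and 0.060 with every transcript. The autosomal one was -0.29, and -0.39 with a pseudocount of 0.1, -0.15 without filter, -0.38 with the minimum of 10, -0.039 and -0.0087 with the scalings (in the same order) and -0.27 for genes with 1 transcript.

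For males against females the X-linked median was -0.19, and -0.21 with a pseudocount of 0.1, -0.11 without filter, -0.25 with the minimum of 10, -0.13 and -0.16 with the scalings, -0.15 for genes with 1 transcript and -0.23 with every transcript. The autosomal one was -0.01, and -0.066 with the minimum of 10, 0.050 and 0.024 with the scalings, 0.024 for genes with 1 transcript and -0.043 with every transcript.

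For metafemales against males the X-linked median was 0.18, and 0.089 without filter, 0.30 with the minimum of 10, 0.44 and 0.54 with the scalings, 0.11 for genes with 1 transcript and 0.25 with every transcript. The autosomal one was -0.50, and -0.56 with a pseudocount of 0.1, -0.32 without filter, -0.39 with the minimum of 10, -0.24 and -0.14 with the scalings, -0.56 for genes with 1 transcript and -0.41 with every transcript.

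Of 23 gene lists 17 (metafemales against females), 15 (males against females) and 12 (metafemales against males) lay outside the central 95% of random lists. With autosomal members only these were 14, 12 and 13. Fat body, cell stress and neuron lists (metafemales against females) and dosage compensation, sex determination and cuticle lists (males against females) went inside, and oxidative phosphorylation (metafemales against males) went outside. With a pseudocount of 0.1 they were 18, 15 and 12, where the testis list of metafemales against females went outside. With a minimum of 10 CPM they were 12 each, where heat shock, cell stress, cuticle, neuron and disc lists of metafemales against females went inside, as did sex determination, cell stress and cuticle (males against females) and cuticle and neurons (metafemales against males), while dosage compensation and ecdysone (metafemales against males) went outside. Depth limits single genes near 0.0133 (female), 0.0178 (male) and 0.0112 (metafemale) CPM, the level of 3 counts.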

Other observations

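The tests on X-linked genes below were chosen before their results were seen, and those on gene lists only after. Transcripts of the sex determination genes differed in how they followed sex. The highest Sxl transcript had 103 CPM in females, 27.3 in males and 86.4 in metafemales, and 1 of the lowest had 25.4, 13.2 and 19.1. Of 3 dsx transcripts, 1 had similar values in females and males (7.28 and 7.16) and 2.95 in metafemales, while the others were lower in both males (3.55 and 3.88) and metafemales (3.91 and 3.98) than in females (9.06 and 9.82). Transcripts of fru ran from 9.03 to 12.5 CPM in females, 5.39 to 7.45 in males and 18.8 to 26.7 in metafemales. Reads appear to be counted for each transcript they overlap, so these values are not measures of single splice forms.

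X-linked genes stood above autosomal genes in metafemales against females. A difference in expression level between the classes was tested by splitting genes into 4 bins by level, with 0.1 CPM added in place of 1. From the lowest to the highest level the offsets were 0.27, 0.49, 0.49 and 0.54 (log2), against 0.44 for all genes on that scale. For developmental point or tissue makeup, X-linked and autosomal members of the same functional list were compared. The median offset was 0.46 over 18 lists (0.21 to 0.91), with 15 positive, among them ribosomal proteins and oxidative phosphorylation. A list does not hold developmental point constant, so this comparison cannot decide on that explanation. The largest offset (5.09) was that of glue and 71E genes, whose X-linked members include the earlier genes ng1 to ng3. A single X segment, as from a strain difference, was tested with 10 blocks of the X, whose lowest offset was 0.28. The tests by level and by block argue against expression level alone and against a single segment alone. Developmental point, tissue makeup and strain differences spread over the X stay open. An additional X copy remains a candidate explanation that was not tested.

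Gene lists standing apart in metafemales against females were tested after they had been seen. Smaller or fewer salivary glands would lower both glue genes and the earlier salivary gland genes, but ng1 to ng4 had a median of 1.99 while the Sgs genes had one of -3.67, which argues against this as the whole cause. The ng genes are X-linked, ng1 and ng2 are near-identical and ng4 was near the floor (0.0354 CPM in metafemales), so this test is a narrow one. The X-linked glue gene Sgs4 was lowered least (-0.97, against -1.53 to -5.06 for the autosomal Sgs genes). The split between ng and Sgs genes therefore follows chromosome class as well as order of expression. An earlier point of the third instar in metafemales and an effect of genotype stay open and were not tested.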
